A study of Rattus norvegicus with 1090 samples.

How the data were processed

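The study dosed male and female Sprague Dawley rats by oral gavage for 5 days with perfluoro-3-methoxypropanoic acid (MOPA), a short perfluorinated ether acid. The vehicle was deionised water, given at 5 ml/kg, and the doses were 0.01, 0.1, 0.3, 1, 3, 10, 30, 100 and 300 mg/kg/day. Tissues were taken 24 hours after the last dose. There were 52 male and 52 female animals, and 12 tissues were measured, 9 of them in both sexes, which gave 21 sets of 1 tissue in 1 sex. The assay was TempO-Seq, in which pairs of detector oligos are ligated on their target RNA and sequenced, with a rat panel of 2654 probes for 2603 genes. A probe reports a 50-base target, so a value says nothing about other exons of a gene. The question the design addresses is the lowest dose at which transcripts move in any tissue.

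Per the labels, the authors aligned the reads to the probe sequences with HISAT2, whose version is not given in the sources used here, and counted the reads of each probe. The deposited tables hold raw read counts per probe and library, without normalization. The tables name probes by gene and number. Of the 2603 genes 2395 matched a current rat RefSeq symbol, 93 matched a RefSeq synonym and 115 matched neither. These names came from the GRCr8 annotation, and no coordinates were used. Total counts per library ran from 522606 to 3111438 with a median of 1416039 in the 1075 libraries used. A total of 3 counts, taken as the floor of detection, stood for 0.964 to 5.74 CPM (the count over the library total, times 1e6) depending on the library. Reads of this assay carry no molecular identifiers, so this floor covers counting error alone.

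The labels record a quality issue for 15 of the 1090 libraries. The submitters had removed 10 as outliers, and 5 had under 50% of reads aligned. These 15 libraries were left out of the main fits and kept in a named alternative. Dose and sex were taken from the labels. Each set of 1 tissue and 1 sex was on its own plate, so plate cannot be separated from tissue or, in the comparisons of the sexes, from sex. Each dose was compared with vehicle of the same plate, and no run or batch within a set is given in the sources used here. No animal was in more than 1 dose group.

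Each set was fitted on its own with edgeR 4.0.16 in R 4.3.3. Probes were filtered by filterByExpr with the dose groups, totals were scaled by TMM, and a quasi-likelihood negative binomial model with 1 mean per dose group was fitted to all libraries of the set. Each dose was compared with vehicle. P values were adjusted over the probes of a set by the Benjamini-Hochberg method, and an adjusted p under 0.05 was called a change. Log2 fold changes are given with their standard error, which is the fold change divided by the square root of the F statistic, and CPM values with their SD. The difference between the sexes was the interaction of sex and the 300 mg/kg/day contrast in a joint fit of both sets of a tissue. In liver and kidney the trend over dose was the slope on the dose group number. Benchmark doses used probes with an adjusted trend p under 0.05 and a mean change of at least 1.5-fold at some dose. Linear, power (exponent 1.1 to 8), exponential and Hill curves were fitted by least squares to log2 CPM with a prior count of 2, and the curve with the lowest AIC was kept. The benchmark dose was the dose at which the curve moved by 1 residual SD, and values outside 0.001 to 300 mg/kg/day were dropped. Its error is the SD of the median over 100 resamples of animals within dose groups.

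A total of 36 gene lists were fixed before the data were examined, and lists with at least 3 measured genes were tested at 300 mg/kg/day with fry from limma 3.58.1. The fry p tests whether the genes of a list move, on balance, in 1 direction, and does not compare the list with other genes. Its p values were adjusted over the lists of a set. A camera test with an estimated correlation between genes was the alternative. The comparisons, thresholds, gene lists and the alternatives in processing were also written before the data were examined. So was the rule for naming genes. It takes the 8 largest rises and 8 largest falls in liver and kidney, and the 4 largest of each in other sets. These needed an adjusted p under 0.05, a mean of at least 10 counts in 1 of the groups and every 300 mg/kg/day library on the same side of the vehicle median. The rule adds up to 4 members of a list under discussion with the smallest adjusted p, and the 5 smallest adjusted p per tissue for the sex difference. Other genes named were chosen after their values were seen. These are the genes named at doses below 300 mg/kg/day, members of lists that missed the threshold, S100a9 and S100a8 in ovary, Vnn1 in male kidney, and Acaa1a, Vnn1, Eci1 and Ccnb2 in the sex comparisons. Some genes that changed, among them genes picked by the rule, are not reported here.

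Transcripts of other tissues were followed with tissue tags, which are probes with a median of at least 2000 CPM in 1 tissue and at least 20 times the highest median elsewhere. A library was called as holding another tissue when the median tag, or the median member of a cell type list, stood 3 or more log2 units above the median of its set. This marked 84 libraries, 24 of them at vehicle or 300 mg/kg/day. For each probe of a set the lower of its mean levels in vehicle and at 300 mg/kg/day was taken. The probe was called open to carry-over when this was under a share of 0.002 of its highest median in another tissue. A probe that rose from a trace level, or fell to one, meets this too. The term therefore does not tell carry-over from a response. Both definitions were made after the data were seen. Probes whose level correlated between tissues of the same animal, by a mean over 0.45 in both sexes, were used to match libraries to animals.

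The alternatives were DESeq2 1.42.0, size factors of the median-of-ratios type (RLE), no filter on low counts, libraries with a quality issue kept, a fit to vehicle and 300 mg/kg/day libraries alone, and each library left out in turn. For trend and benchmark dose they also included the dose itself as the scale, the fit without the 300 mg/kg/day group, a larger response size, another prior count and no fold filter. Fits without open probes and without libraries holding another tissue were added after the data were seen. Splits of the same libraries into groups of the same sizes were drawn 100 times, or 50 times for the sex difference. The tests were checked on simulated data. Of 2381 calls edgeR made at 300 mg/kg/day over the 21 simulated sets, 110 (4.62%) were false, and at 4-fold it recovered a median of 87.9% of changed probes, at 2-fold 56.7% and at 1.5-fold 22.4%. The simulated probes varied independently of each other and held no transcripts of other tissues. These shares therefore need not hold for the real libraries. The median of 200 simulated benchmark doses was 0.88 to 1.19 times the true value in each setting, but single probes scattered widely at 100 mg/kg/day. Quartiles there were 48.8 and 195 for the Hill curve and 52.3 and 191 for the exponential, with an estimate for 162 and 181 of the 200 probes. Each simulated curve was scaled to move by 1 residual SD at its true dose. At a true dose of 3, and for the power curve at 30, changes at 300 mg/kg/day were then far larger than real ones. The selection of probes by trend and fold was not simulated. Recovery at these doses therefore says little about the reported benchmark doses. Figures were drawn with matplotlib 3.10.9. Reads, body and organ weights, clinical chemistry and plasma concentrations are not analysed here. The order of the rows was tested by 36 marker genes, of which 31 peaked in their own tissue against at most 9 in 1000 random orders.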

Results

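The 1090 libraries came from 52 male and 52 female rats, and 1075 of them entered the comparisons. Each of the 21 sets had 7 or 8 vehicle libraries, 3 to 5 libraries at each lower dose, and 5 male or 4 female libraries at 300 mg/kg/day, with 3 in female kidney and female spleen. Library totals ran from 522606 to 3111438 counts. The comparisons address which transcripts, tissues and doses responded to 5 days of MOPA, a perfluorinated ether acid, and whether the sexes differed. Counts of changed genes are counts of probes. Some probes of genes that are abundant in another tissue sat at a trace level in vehicle or at 300 mg/kg/day. These, here called open to carry-over, are named as such, because such traces moved in either direction at 300 mg/kg/day. A rise from a trace level earns the name whatever its cause. The probe Hsd3b shares its name with 2 RefSeq genes.

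Male liver at 300 mg/kg/day raised genes of peroxisomal and mitochondrial fatty acid oxidation. Of 37 probes on the list of PPARalpha targets and fatty acid oxidation, 19 rose and none fell, 18 did not pass, and 22 rose and 1 fell when adjusted over the list alone (fry adjusted p = 2.8e-11, and 0.000232 with an estimated correlation). Ehhadh rose from 42.5 ± 12.3 CPM in vehicle (SD, n = 7) to 766 ± 274 CPM (n = 5), a log2 change of 4.17 ± 0.34 (SE, adjusted p = 1.34e-13). Cyp4a1 rose by 4.28 ± 0.40 from 78.9 to 1530 CPM, Vnn1 by 3.67 ± 0.26, Eci1 by 3.65 ± 0.30 and Acaa1a by 3.51 ± 0.32, each in 5 of 5 libraries. Acot1, a probe open to carry-over, rose from 0.224 to 17.2 CPM.

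Drug metabolism genes in male liver moved less evenly. On the CAR and PXR list 4 of 18 probes rose and none fell, also when adjusted over the list alone, among them Aldh1a1 (3.11 ± 0.41), Ugt1a1 (1.09 ± 0.23), Cyp3a23-3a1 (0.91 ± 0.31) and Cyp2b1 (3.26 ± 0.43, open to carry-over). Its fry adjusted p was 0.00146, but 0.485 with an estimated correlation. Among 3 AHR targets Cyp1a2 fell by 1.01 ± 0.28 and Cyp1b1, open to carry-over, rose by 3.49 ± 0.54 (fry adjusted p = 7.05e-05, and 0.485 with an estimated correlation). Of 12 hepatocyte markers 3 fell, Ahsg (-0.98 ± 0.25), Ass1 (-1.42 ± 0.44) and Tf (-0.55 ± 0.17), with an adjusted p of 0.00802, or 0.61 with an estimated correlation. Of 9 bile acid genes Amacr fell by 0.94 ± 0.22 (list adjusted p = 0.0023, and 0.61 with an estimated correlation). Scd1 (1.43 ± 0.37), Me1 (1.59 ± 0.33) and S100a9 (2.52 ± 0.45) rose. The other falls named by the rule were Abcg5 (-2.17 ± 0.59), Syne2 (-2.03 ± 0.55), C1s (-1.53 ± 0.30), Abl1 (-1.52 ± 0.51), Stac3 (-1.31 ± 0.30), C1r (-1.27 ± 0.41), LOC679346 (-1.20 ± 0.31) and Snap25 (-2.13 ± 0.35, open to carry-over).

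Transcripts of adrenal and heart also stood higher in male liver. Hsd3b rose from 1.32 to 212 CPM, Myl2 from 0.151 to 33.9 CPM and Star from 0.0762 to 16.1 CPM, and Cyp11a1 was at 0 counts in all 7 vehicle libraries against 7.75 CPM. Cyp17a1 (3.15 ± 0.53) and Mlf1 (4.33 ± 0.79) rose too, and of these only Cyp17a1 was not open to carry-over. The steroid synthesis list had 3 of 5 probes up, and 3 up and 2 down when adjusted over the list alone (adjusted p = 5.07e-11, and 0.00826 with an estimated correlation), but 0.901 without probes open to carry-over. The adipocyte list (1 of 4 up, adjusted p = 0.00544) was at 0.265 without such probes and at 0.721 with an estimated correlation. The kidney transporter list (1 of 3 up, 0.037) and the estrogen list (1 of 3 down, 0.0343) were each at 0.742 with an estimated correlation. In total 167 probes changed, 107 higher and 60 lower. Leaving out 1 library gave 78 (replicate 158, marked by its testis tags), 100 (156) or 336 (159). The median of the 5 testis tags in 158 stood 3.1 log2 units above that of the set. Some of these tags rose with dose in male liver, so the mark does not tell testis tissue from a response. Without 1 library the adjusted p of Syne2 reached 0.054 (158), of Abl1 0.135 (155), of C1r 0.132 (156), of Cyp3a23-3a1 0.158 (156), of Ass1 0.103 (156), of Tf 0.126 (158), and of Cyp1a2 0.0664 (vehicle 111).

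Single genes of fatty acid oxidation also rose in male liver at lower doses, where the lists were not tested. At 100 mg/kg/day 18 probes changed, 16 higher and 2 lower, with Cyp4a1 up by 3.46 ± 0.39 (78.9 to 867 CPM, adjusted p = 2.82e-08, n = 5), Ehhadh by 2.62 ± 0.32, Acaa1a by 2.05 ± 0.30, Vnn1 by 1.69 ± 0.25 and Eci1 by 1.46 ± 0.29. Cyp2b1 (2.11 ± 0.44, open to carry-over) and Ugt1a1 (1.00 ± 0.23) rose as well. At 30 mg/kg/day 25 probes changed (20 higher, 5 lower, n = 4; DESeq2 38 and 24), among them Cyp4a1 (2.05 ± 0.39, adjusted p = 0.0071), Ugt1a1 (1.09 ± 0.24), Decr1 (1.55 ± 0.35) and Aldh1a1 (1.72 ± 0.42). The count at 30 mg/kg/day rested on single animals: it was 0 without replicate 147 (where Cyp4a1 had an adjusted p of 0.269), 1 without 149, 57 without 146, and 3, 4 or 5 without vehicle 111, 110 or 114. At 100 mg/kg/day it was 11 without replicate 154. No probe changed at 10 mg/kg/day. At 0.1 mg/kg/day 12 did (5 higher, 7 lower), with 372 at an unadjusted p under 0.05 against 78 expected by chance. The counts thus did not rise steadily with dose. Over all doses 88 probes had a trend. Their median benchmark dose was 113 ± 34.1 mg/kg/day (75 probes), with quartiles of 21.3 and 181. This median was 38.2 without replicate 146, 38.9 without 158, 47.4 without 156, 48.3 without 144, 51.9 without 157, 58.1 without 115, 60.7 without 140, 64.6 without 152, 67.4 without 155, 69.7 without 135 and 72.1 without 141 or 159. For the PPARalpha list it was 92.0 (16 probes, 10.7 to 273). For CAR and PXR it was 11.1, the value of Ugt1a1, between Aldh1a1 (0.002) and Cyp2b1 (95.9, open to carry-over). The value of Aldh1a1 lies below the lowest dose given, so these 3 probes do not rank the lists by dose.

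**Figure D1:**
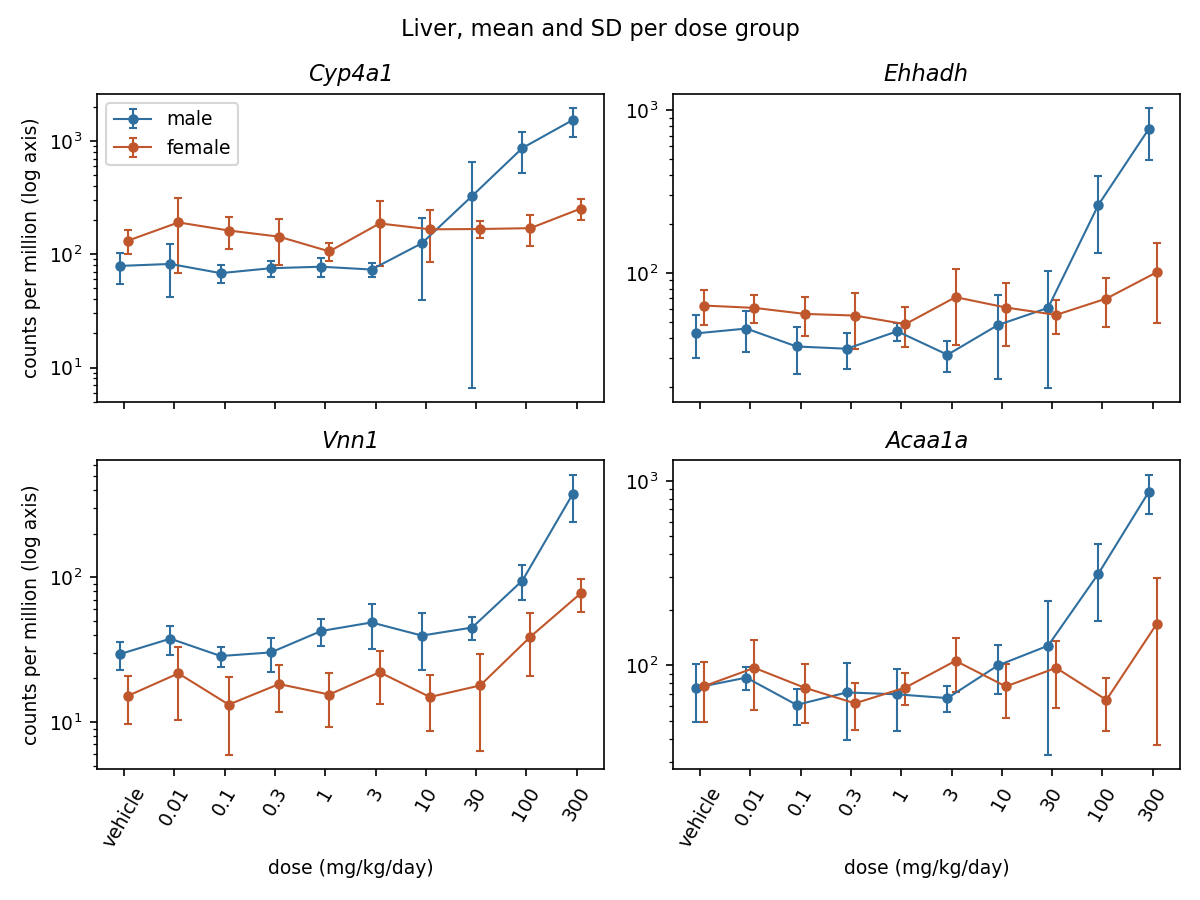
Mean CPM of Cyp4a1, Ehhadh, Vnn1 and Acaa1a in liver by dose on a log axis. Points are group means and bars the SD of 4 to 8 animals in each sex. Bars that would reach 0 or below are shortened. In males Cyp4a1 stood at 78.9 CPM in vehicle, 867 at 100 and 1530 at 300 mg/kg/day.

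Female liver at 300 mg/kg/day changed 45 probes, 29 higher and 16 lower, and 3 of 36 PPARalpha probes rose (9 when adjusted over the list alone). Vnn1 rose from 15.2 ± 5.54 to 77.6 ± 20.2 CPM (log2 change 2.36 ± 0.35, adjusted p = 7.78e-06, 4 of 4 libraries), Eci1 by 1.19 ± 0.30 and Acaa1a by 1.11 ± 0.31. Cyp4a1 (0.94 ± 0.31, adjusted p = 0.09) and Ehhadh (0.68 ± 0.28, 0.202) did not pass, and nor did the list (fry 0.0524, and 0.316 with an estimated correlation). Elovl6, a fatty acid elongase, fell from 200 ± 120 to 30.4 CPM (-2.71 ± 0.55, adjusted p = 0.00269), and Gbe1 (-0.99 ± 0.21), Slc26a1 (-1.07 ± 0.25), Gulo (-1.09 ± 0.29), Slc13a4 (-1.18 ± 0.30), Tubb2a (-1.19 ± 0.30), Nrep (-1.98 ± 0.51) and St6galnac2 (-1.26 ± 0.31, open to carry-over) fell. Klra17 (2.20 ± 0.40), Cyp17a1 (2.14 ± 0.46), Spink1 (2.30 ± 0.65) and Igfbp6 (2.19 ± 0.56) rose.

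Acute phase genes rose in female liver, mostly in 1 animal. Of 18 probes 3 rose, and 7 when adjusted over the list alone (adjusted p = 0.00128, and 0.0853 with an estimated correlation): Hp (1.80 ± 0.50), Lcn2 (2.07 ± 0.59) and A2m (2.04 ± 0.59), while Stat3 missed (1.02 ± 0.30, adjusted p = 0.0501). Without replicate 208 the adjusted p was 0.718 for Hp, 0.497 for Lcn2, 0.656 for Acaa1a and 0.902 for A2m, whose change became -0.27. The kidney injury list (1 of 8 up, adjusted p = 0.00384) was at 0.154 and the glucocorticoid list (0 of 8 over all probes, 1 alone, 0.0154) at 0.302 with an estimated correlation. Of 4 steroid synthesis probes 2 rose (0.000205, and 0.0514 with an estimated correlation), with Hsd3b at 168 against 2.73 CPM and Star at 8.99 against 1.22, and Myl2 rose from 0.523 to 55.6 CPM, all open to carry-over. The count was 19 without replicate 210, which also ended the calls of Igfbp6 (0.771), Nrep (0.13), St6galnac2 (0.104), Tubb2a (0.106) and Slc13a4 (0.0907). Gulo stood at 0.11 and Eci1 at 0.17 without 211, and Spink1 at 0.166 without 208. DESeq2 called 75 probes, 38 higher and 37 lower. At 100 mg/kg/day the 1 probe that changed was Hmgb2 (1.61 ± 0.26, adjusted p = 0.000311, open to carry-over), and Vnn1 did not pass (1.36 ± 0.34, 0.161). The trend held for 7 probes (by DESeq2 5 higher and 2 lower; 4 without replicate 208, 210 or 211 of 300 mg/kg/day, 12 without 191 of 3 mg/kg/day), with a median benchmark dose of 123 ± 19.0 mg/kg/day.

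The liver response to 300 mg/kg/day differed between the sexes in 73 probes by the interaction test, 54 with a higher change in males and 19 in females. The excess in males was 3.50 ± 0.45 for Ehhadh (adjusted p = 2.96e-08), 3.35 ± 0.53 for Cyp4a1 (5.67e-06), 2.46 ± 0.45 for Eci1 and 2.42 ± 0.46 for Acaa1a, while for Vnn1 it did not pass (1.32 ± 0.45, adjusted p = 0.068). St6galnac2 (4.88 ± 0.71), Fam183b (5.45 ± 0.87) and Hspa1l (7.78 ± 1.24) complete the 5 smallest p values and were open to carry-over in both sexes. Both sexes shared 12 higher probes, Vnn1, Eci1 and Acaa1a among them, against 1.89 for independent lists. Of these 12 Hmgb2, Hsd3b, Myl2, Star and Prkar2b were open to carry-over in both livers and Igfbp6 in males. They also shared 3 lower probes against 0.56. Without 1 library the count of 73 became 46 (male 158), 177 (male 159), 121 (male vehicle 109), 45 (female 208), 48 (female 211) or 114 (female vehicle 160).

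In male kidney at 300 mg/kg/day some genes of fatty acid oxidation rose and some of cell division fell. Acaa1a rose from 247 ± 71.6 to 1020 ± 271 CPM (log2 change 2.04 ± 0.20, adjusted p = 2.15e-10, 5 of 5 libraries). Ehhadh (1.38 ± 0.27), Cyp4a1 (1.30 ± 0.22), Eci1 (1.28 ± 0.17) and Vnn1 (1.12 ± 0.28, 0.0739 without replicate 156) rose too. On the PPARalpha list 9 of 43 probes rose and 1 fell, and 10 rose when adjusted over the list alone (fry adjusted p = 0.000102, and 0.176 with an estimated correlation). Of 26 cell cycle probes 4 fell and 1 rose, with Ccnb2 from 87.8 to 40.1 CPM (-1.13 ± 0.18), Pcna (-0.69 ± 0.12) and Kif20a (-1.21 ± 0.37) down and Cdc6 (2.35 ± 0.73) up. The list did not pass in 1 direction (0.0592) but did for change in either (0.000277). Hmmr (-1.77 ± 0.34) and Cdkn3 (-1.16 ± 0.36), also of the dividing cell, fell. Of 12 fatty acid synthesis probes 4 rose, 6 when adjusted over the list alone: Fasn (0.76 ± 0.14), Scd (1.56 ± 0.46), Acaca (0.79 ± 0.25) and Elovl5 (0.39 ± 0.12), with an adjusted p of 5.07e-05, or 0.176 with an estimated correlation. Of 15 cholesterol synthesis probes Fdps (0.61 ± 0.17) and Fdft1 (0.37 ± 0.12) rose (0.00241, and 0.397 with an estimated correlation).

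The CAR and PXR list had 6 of 15 probes up in male kidney (fry adjusted p = 8.79e-08, and 0.0256 with an estimated correlation), at low levels: Cyp3a1 from 1.19 to 16.0 CPM and Cyp2c6v1 from 8.27 to 42.9, both open to carry-over, and Slco1a2 from 1.92 to 11.4. Replicate 159 held liver transcripts. Without libraries holding another tissue the adjusted p was 0.000329 for Cyp3a1, 0.000719 for Cyp2c6v1 and 0.000564 for Slco1a2, and the list was not tested without them. The largest rises were near the floor in vehicle. Serpinb2, open to carry-over, had 0 counts in all 8 vehicle libraries against 7.48 CPM, Amy2a3 rose from 0.109 to 11.8, Pkm from 0.201 to 10.0, Kcnd2 from 0.209 to 9.20, Reg3g from 0.190 to 8.25 and Ampd1 from 0.283 to 8.33, and Ugt2b1 (0.291 to 10.2) and Sult2a2 (1.01 to 26.9, 7.84e-07 without libraries holding another tissue), open to carry-over, moved with them. Abundant transcripts that fell were Hao2 (-1.18 ± 0.35), LOC100134871 (-1.67 ± 0.43), LOC689064 (-1.49 ± 0.34), LOC679794 (-1.19 ± 0.24) and LOC287167 (-1.16 ± 0.33), and Aebp1 fell by 1.22 ± 0.30. Krt18 rose by 1.48 ± 0.30 on the kidney injury list (1 of 11, 2 alone) and S100a9 by 1.60 ± 0.37 on the neutrophil list (1 of 8, 3 alone). The adjusted p of these lists was 0.0106 and 0.00241, or 0.521 and 0.386 with an estimated correlation. The sex-biased list (3 up and 1 down of 6, 0.0233) and the adipocyte list (1 of 4 up, 0.0233) were each at 0.521 so tested. Star (1.13 ± 0.28) and Cyp11a1 (1.30 ± 0.37) rose on the steroid list (2 of 3, 0.000124, and 0.176 with an estimated correlation), open to carry-over.

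In total 148 probes changed in male kidney, 103 higher and 45 lower, and no 1 library moved this count more than 1.5-fold. DESeq2 called 193, 109 higher and 84 lower. Without 1 library the adjusted p of Hao2 reached 0.113 (replicate 157), of LOC287167 0.0556 (155), of Cdkn3 0.103 (vehicle 110), of Kif20a 0.0832 (155), of Cdc6 0.106 (157), of Acaca 0.148 (157), of Elovl5 0.17 (158), of Scd 0.102 (159), of Fdps 0.072 (156), of Fdft1 0.177 (156) and of Cyp11a1 0.0854 (159). At 100 mg/kg/day 21 probes changed, 17 higher and 4 lower: Acaa1a (1.72 ± 0.20, adjusted p = 4.49e-08) and Eci1 (0.86 ± 0.17) rose and Ccnb2 (-1.05 ± 0.18) and Mki67 (-0.82 ± 0.21) fell. That count was 7 without replicate 153, 11 without 151, 34 without 154, and 12 or 13 without vehicle 109 or 110. The trend held for 110 probes, 68 without replicate 157 of 300 and 174 without 129 of 0.3 mg/kg/day. The median benchmark dose was 99.7 ± 31.9 mg/kg/day over 93 probes, 23.9 for the PPARalpha list (7 probes, 10.1 to 98.5), 45.0 for cell cycle (5 probes) and 128 for CAR and PXR (4 probes).

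In female kidney at 300 mg/kg/day (n = 3) Vnn1 rose from 522 ± 81.5 to 2090 ± 1390 CPM (2.00 ± 0.27, adjusted p = 2.16e-06, 3 of 3 libraries), Acaa1a by 1.62 ± 0.24 and Eci1 by 0.93 ± 0.19. The PPARalpha list had 6 of 43 probes up, and 9 up and 1 down when adjusted over the list alone (fry adjusted p = 0.0279, and 0.164 with an estimated correlation). Glucocorticoid response genes rose in 3 of 8 probes (4 alone, 0.0192, and 0.122 with an estimated correlation): Fkbp5 (1.85 ± 0.34), Pck1 (1.51 ± 0.41) and Cebpd (1.09 ± 0.29). Without replicate 210 these stood at 0.818, 0.935 and 0.877, Slc13a4 (1.54 ± 0.40) at 0.658 and Oxct1 (-0.55 ± 0.13) at 0.145. Skeletal muscle transcripts fell (1 of 6 probes, 3 alone, adjusted p = 0.000724, and 0.0244 with an estimated correlation), with Myh1 down by 3.52 ± 0.61, and Mylpf, not on that list, fell by 1.82 ± 0.38. Myh1, like Tg (-1.90 ± 0.25), Hsd3b (4.10 ± 0.62), Myl2 (2.26 ± 0.47), Star (2.71 ± 0.72) and LOC259245 (2.39 ± 0.59), was open to carry-over. Without 1 library Mylpf stood at 0.0621 (209) and, without 208, Eci1 at 0.148, Myl2 at 0.13, Star at 0.304 and LOC259245 at 0.342.

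The count in female kidney was 24, 20 higher and 4 lower, 13 without replicate 210 and 40 without 209, and DESeq2 called 42 (29 higher, 13 lower). At 100 mg/kg/day Sec24d rose (0.71 ± 0.10, adjusted p = 8.83e-06) and Abhd6 fell (-0.73 ± 0.16, 0.0254). That count of 2 became 18 without vehicle 162, which held adipocyte transcripts, 4 without 204 or 207, and 1 without 206 or vehicle 160, 164 or 166. Replicates 206 and 207 held adipocyte transcripts too. At 0.3 mg/kg/day 80 probes changed, 53 higher and 27 lower, with Sec24d at 0.72 ± 0.10, Dbp at 1.11 ± 0.22 and Ucp1, high in vehicle 162, at -7.17 ± 1.75. The count was 3 without replicate 178, 9 without 181, 25 without 182, 154 without 179, 207 without 180, and 34, 44, 47 or 49 without vehicle 166, 162, 164 or 167. The trend held for 4 probes (2 without replicate 210), with a median benchmark dose of 82.3 ± 32.2 mg/kg/day that was 0.0016 without that animal, and 85.4 for 3 PPARalpha probes.

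The kidney response differed between the sexes in 51 probes. The interaction did not pass for Acaa1a (0.40 ± 0.33, adjusted p = 0.532), Vnn1 (-0.90 ± 0.41, 0.232) and Ccnb2 (-0.74 ± 0.41, 0.33), whose own change in females was -0.43 ± 0.41 (0.743). Sec24d rose in females by 0.71 ± 0.11 and not in males (interaction -0.92 ± 0.16, adjusted p = 0.000142). In females it stood at 608, 606 and 605 CPM at 0.3, 100 and 300 mg/kg/day, against 370 in vehicle. The rise was thus no larger at 300 than at 0.3 mg/kg/day. Aebp1 fell in males by 1.22 ± 0.30 (interaction -1.94 ± 0.39). Tg (6.33 ± 0.65), Myh4 (7.20 ± 1.24) and Myh1 (5.80 ± 1.01), open to carry-over in both sexes, had the other smallest p values. Their counts fell under the filter in male kidney, so they have no test in males alone. Both sexes shared 7 higher probes, Acaa1a, Eci1 and Vnn1 and also Hsd3b and Star, open to carry-over in both, among them, against 0.78 for independent lists. The count of 51 was 16 without male 157, 79 without male 156, 6 without female 210 and 32 without female 208.

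**Figure D2:**
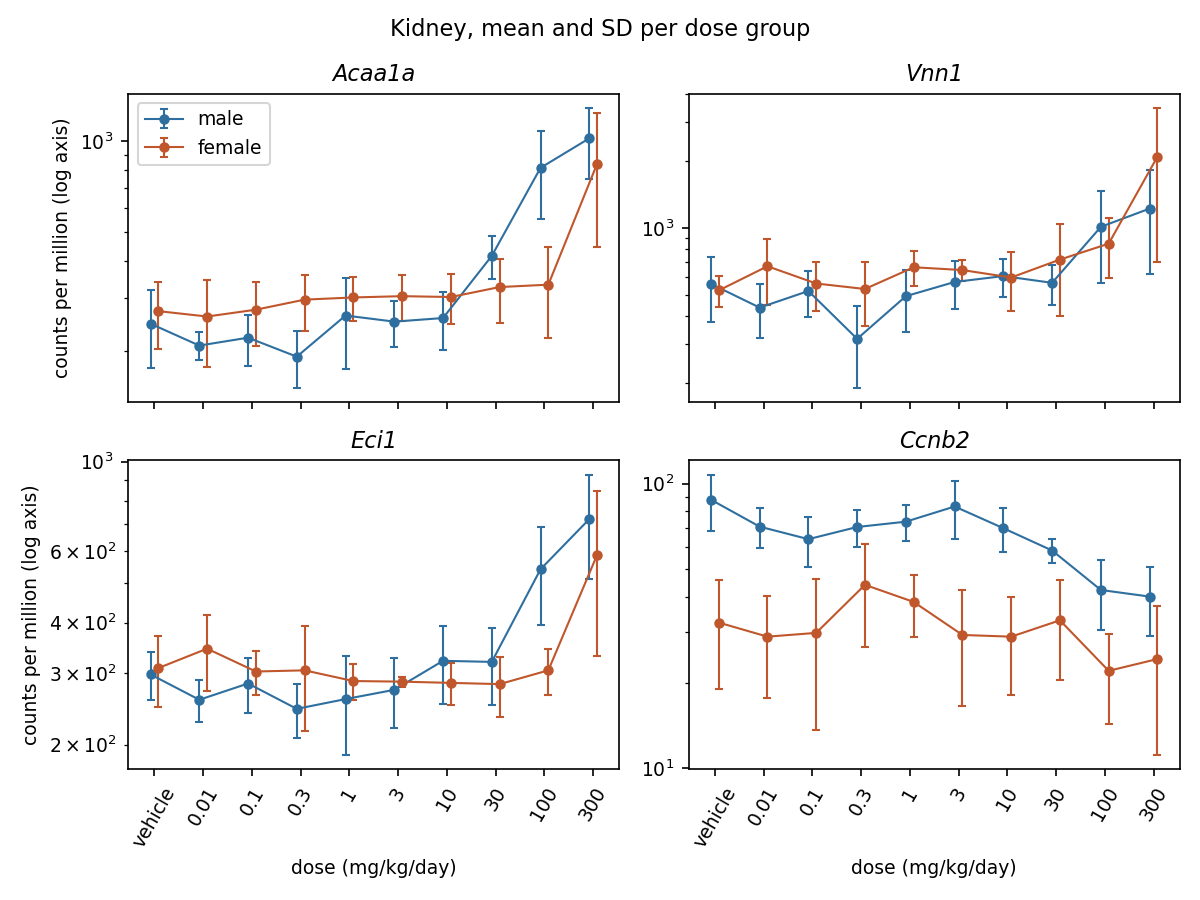
Mean CPM of Acaa1a, Vnn1, Eci1 and Ccnb2 in kidney by dose on a log axis, with points for group means and bars for the SD of 3 to 8 animals in each sex; bars that would reach 0 or below are shortened. Acaa1a stood at 1020 CPM in males and 839 CPM in females at 300 mg/kg/day, against 247 and 272 CPM in vehicle.

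In female adrenal gland cholesterol synthesis genes rose. Of 16 probes 7 rose and none fell, 12 when adjusted over the list alone, with a median log2 change of 1.28 (fry adjusted p = 0.00412, and 0.169 with an estimated correlation). Acat2 rose from 186 ± 77.4 to 644 ± 243 CPM (1.79 ± 0.34, adjusted p = 0.000625, 4 of 4 libraries), Fdps by 1.83 ± 0.34, Cyp51 by 1.93 ± 0.44 and Fdft1 by 1.09 ± 0.23. Cpt2 (0.66 ± 0.14) and the clock gene Dbp (0.89 ± 0.25; list 1 of 7, 2 alone, 0.0119, and 0.227 with an estimated correlation) rose. Cell cycle genes fell in 3 of 26 probes, Mcm3 (-1.09 ± 0.29), Ccna2 (-1.47 ± 0.42) and Plk1 (-1.43 ± 0.44), with an adjusted p of 0.0186, or 0.474 with an estimated correlation. Of 5 T cell markers Cd3d fell (-1.80 ± 0.45, open to carry-over; list 0.00241, and 0.169 with an estimated correlation), and Cxcr4 (-1.96 ± 0.48), Srd5a1 (-1.93 ± 0.54), Ung (-1.91 ± 0.58) and Gbp4 (-1.81 ± 0.58) fell. The 4 largest rises, Myl2 (3.94 ± 0.96), Cfi (3.85 ± 0.91), Fabp1 (3.28 ± 0.99) and Cyp3a2 (2.94 ± 0.49), were open to carry-over, and replicate 209 held liver transcripts, without which Cfi stood at 0.134 and Fabp1 at 0.661.

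The count in female adrenal gland was 131 (86 higher, 45 lower), 55 without replicate 211 and 76 without 208, and 27 with the quality-issue library kept. Without 1 library the adjusted p of Mcm3 reached 0.0619 (208), of Ccna2 0.0849 (209), of Plk1 0.129 (210), of Dbp 0.0833 (211), of Cd3d 0.063 (211), of Srd5a1 0.0876 (210), of Ung 0.126 (211) and of Gbp4 0.123 (211). Male adrenal gland changed 17 probes (7 higher, 10 lower) at 300 mg/kg/day, with Olfm1 (2.19 ± 0.51), Gata3 (1.51 ± 0.33), Hist1h4a (1.37 ± 0.16) and Bex1 (0.99 ± 0.26) up and Spc24 (-1.24 ± 0.29) and Cblb (-1.15 ± 0.26) down. Tg (-2.83 ± 0.23) and Tnnc2 (-1.72 ± 0.37) fell, open to carry-over, and of 5 thyroid genes 1 fell (adjusted p = 5.08e-05, and 0.00554 with an estimated correlation). The count was 8, 10 or 11 without replicate 157, vehicle 110 or replicate 159, and DESeq2 called 31 (16 higher, 15 lower). With the quality-issue libraries kept none passed. Of these genes all but Hist1h4a and Tg lost the call without 1 library, with adjusted p up to 0.151 for Bex1 (158). In the sex difference test 32 probes passed, led by Hmgb2 (1.83 ± 0.26), Nmt1 (-0.88 ± 0.16) and Hsdl2 (-0.99 ± 0.21), and by Tg (-10.4 ± 0.64) and Ckm (-4.04 ± 0.89), open to carry-over in both sexes. It was 17 without male 157 or female 211, 14 without female 210 and 19 without female 208.

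In the main fit female thymus had the highest count of all sets, 206 probes (90 higher, 116 lower), but not with the quality-issue libraries kept. Hist1h4a rose from 10600 ± 2230 to 45700 ± 26900 CPM (2.11 ± 0.23, adjusted p = 4.67e-09, n = 7 and 4, 4 of 4 libraries), Cd74 from 3220 to 11700 CPM (1.86 ± 0.23), Igh-6 by 1.72 ± 0.58 and Polr1e by 1.56 ± 0.44. Of 34 cell cycle probes 7 fell, among them Ccne2 (-1.47 ± 0.28), Ccna2 (-0.94 ± 0.24), Pcna (-0.89 ± 0.24) and E2f1 (-0.88 ± 0.25), but the list did not pass (fry 0.0865, and 0.943 with an estimated correlation). Of 13 cholesterol synthesis probes 5 fell (8 down and 1 up alone), with Idi1 (-0.75 ± 0.20), Nsdhl (-0.57 ± 0.16) and Insig1 (-0.54 ± 0.13) down and an adjusted p of 0.00136, or 0.411 with an estimated correlation. Of 17 unfolded protein response probes 3 rose, with Herpud1 at 0.70 ± 0.15 and Atf4 at 0.92 ± 0.25, and the list did not pass (0.0886). Steroid genes fell (3 of 5, 4 alone, adjusted p = 5.31e-08, and 0.00276 with an estimated correlation), with Hsd3b (-3.25 ± 0.30), Star (-3.16 ± 0.32), Cyp11a1 (-3.44 ± 0.38) and the muscle gene Pgam2 (-2.91 ± 0.62) open to carry-over. Vehicle 164 held skeletal muscle transcripts, and without it Pgam2 had an adjusted p of 0.0147. The count was 75 without replicate 211 and 130 without 210. Without 210 Igh-6 stood at 0.533, Pcna at 0.0806, E2f1 at 0.0959 and Idi1 at 0.0894, and without 211 Polr1e stood at 0.107, Atf4 at 0.185, Insig1 at 0.0618 and Nsdhl at 0.0953.

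Male thymus changed 45 probes (26 higher, 19 lower), with Kif23 (1.01 ± 0.28), Mcm3 (0.52 ± 0.14), Ncapd2 (1.21 ± 0.33) and Ssbp2 (1.27 ± 0.31) up. Myl2 (1.56 ± 0.43) and Cnn1 (1.56 ± 0.42) rose and Hsd3b (-1.49 ± 0.19), Cyp11a1 (-1.54 ± 0.34), Star (-0.93 ± 0.26), Pgam2 (-1.52 ± 0.38) and Tcfl5 (-1.76 ± 0.51) fell, all open to carry-over, and the steroid list fell (2 of 5, 3 alone, 0.00255, and 0.107 with an estimated correlation). All of these but Hsd3b lost the call without some library, with adjusted p up to 0.352 for Ncapd2 (158). The count was 1, 97, 5 or 4 without replicate 155, 156, 157 or 158, and 7, 8, 3, 73, 6, 26 or 23 without vehicle 107, 108, 109, 111, 112, 113 or 114. DESeq2 called 70 (31 higher, 39 lower). The sex difference in thymus (13 probes) was led by open probes, Snap25 (3.08 ± 0.55), Star (2.21 ± 0.40), Hsd3b (1.75 ± 0.32) and Slc1a2 (1.70 ± 0.36), and by Mylpf (3.24 ± 0.78, adjusted p = 0.906 without female vehicle 164, which held muscle transcripts). It was 33 without female 208 or 209, 8 without male vehicle 107 or 112, male 157 or female vehicle 161, 7 without female vehicle 163, 6 without male vehicle 109, 111 or 114, male 158 or female vehicle 164, 5 without female 210 and 4 without male 159 or female 211.

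Spleen gave 49 probes in males (22 higher, 27 lower) and 4 in females (2 and 2, 184 at an unadjusted p under 0.05). Male spleen lowered the collagens Col1a2 (-0.70 ± 0.19) and Col4a1 (-1.34 ± 0.35), whose adjusted p reached 0.15 and 0.127 without 158. Hsd3b (4.72 ± 0.48), Star (1.14 ± 0.25), Cyp11a1 (2.84 ± 0.46), Inhba (2.80 ± 0.44) and Hspa1l (3.44 ± 0.82, 0.0596 without 155) rose and Ckm (-1.75 ± 0.32), Myl2 (-1.62 ± 0.30) and Tg (-1.38 ± 0.26) fell, all open to carry-over. The steroid list (2 of 5, 3 alone, 2.78e-05, and 0.0172 with an estimated correlation) was at 0.424 without such probes. The count was 24, 17, 23, 26 or 105 without replicate 155, 156, 157, 158 or 159, and 32 without vehicle 107. In females Hsd3b (2.38 ± 0.48, 0.0659 without 211) and Cyp4a8 (1.88 ± 0.43, 0.969 without 209) rose and Myl2 (-3.26 ± 0.30) and Ckm (-1.91 ± 0.33) fell, open to carry-over, and the skeletal muscle list fell (1 of 6, 2 alone, 0.000205, and 0.00489 with an estimated correlation). The sex difference (5 probes) held Hexa (1.63 ± 0.33), Hgf (-1.69 ± 0.37), Igfbp7 (-0.88 ± 0.20), Cenpk (2.91 ± 0.68) and Cps1 (2.95 ± 0.69). It was 0 without female 211, 1 without male 157, 3 without female 209, 8 without male vehicle 110 or 112 or female vehicle 165, 9 without female vehicle 162 and 13 without male 159. DESeq2 called 21 (16 higher in males, 5 lower, against 3 and 2), and 316 probes had an unadjusted p under 0.05.

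Female heart changed 60 probes (48 higher, 12 lower), and 4 of the smooth muscle markers that led them lost the call without 1 animal. All 5 rose (fry adjusted p = 0.00903, and 0.109 with an estimated correlation), Acta2 from 58.4 ± 13.0 to 1360 ± 2380 CPM (4.54 ± 0.55), with Tagln (4.71 ± 0.60), Myh11 (4.85 ± 1.06) and Cnn1 (6.57 ± 0.95, open to carry-over). Replicate 211 held adipocyte and smooth muscle transcripts, and 210 smooth muscle. Without 211 the changes of these were 1.59, 1.72, 1.33 and 3.42, at an adjusted p of 0.0547, 0.081, 0.755 and 0.0945. Without it the adjusted p of Thrsp (3.37 ± 0.98) was 0.954, of S100a9 (2.15 ± 0.38) 0.076, of Mcpt8l2 (-2.86 ± 0.72) 0.0945, of Atp5s (-1.49 ± 0.39) 0.14 and of S1pr3 (-1.14 ± 0.33) 0.242. Glucocorticoid response genes rose in 2 of 7 probes (5 alone, 0.00366, and 0.109 with an estimated correlation), Fkbp5 by 1.45 ± 0.29 and Cebpd by 1.57 ± 0.34 (0.0714 without 210). The immediate early list moved up with 0 of 13 probes passing (0.00347, and 0.109 with an estimated correlation). RT1-A2 fell by 1.57 ± 0.32, a probe whose level correlated on average between tissues of the same animal. The count was 9 without 211, 96 without 210 and 116 without 209, and DESeq2 called 103 (71 higher, 32 lower).

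Male heart changed 2 probes, with 169 at an unadjusted p under 0.05. Acot2, which hydrolyses acyl-CoA in mitochondria, rose from 73.8 ± 24.8 to 211 ± 30.9 CPM (1.51 ± 0.30, adjusted p = 0.00717, 5 of 5 libraries), and Hsd3b, open to carry-over, by 1.36 ± 0.17. The sex difference in heart (31 probes) was led by Tagln (-5.25 ± 0.72), Acta2 (-4.71 ± 0.68), Tpm2 (-4.55 ± 0.70), Cnn1 (-7.79 ± 1.26, open to carry-over in both sexes) and Net1 (-2.17 ± 0.42). Without female 211 it was 0, with 75 or 72 without female 209 or 210 and 49 or 50 without male vehicle 107 or 113. In all hearts together 400 probes had an unadjusted p under 0.05 for this difference and DESeq2 called 83.

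Lung and thyroid carried few changes that held without single animals. Male lung changed 23 probes (18 higher, 5 lower), 4 without replicate 155, 41 without 159 and 14 or 15 without vehicle 113 or 111, and DESeq2 called 44 (28 higher, 16 lower). Replicates 155 and 156 held adrenal transcripts, and Hsd3b (6.06 ± 0.81), Cyp11a1 (5.52 ± 0.78), both open to carry-over, Star (5.03 ± 0.67), Scarb1 (2.86 ± 0.51) and Prdx3 (1.36 ± 0.24) led the rises. Without 155 Cyp11a1 stood at an adjusted p of 0.333, Star at 0.08, Scarb1 at 0.465, Prdx3 at 0.252, Cd3g (-1.27 ± 0.33) at 0.162 and the open probes LOC100912222 (-1.09 ± 0.28) at 0.159 and Mapk10 (-1.73 ± 0.39) at 0.08. Hist1h4a (1.32 ± 0.30) and Sertad1 (0.90 ± 0.20) rose, at 0.0671 and 0.064 without 156, and Snap25, open to carry-over, fell by 2.15 ± 0.28. Female lung changed 6 probes (5 higher, 1 lower), with S100a9 from 844 to 2810 CPM (1.74 ± 0.37) and Cdo1 (1.19 ± 0.28) up and Hsd3b (-1.36 ± 0.20, open to carry-over) down. That count was 2 without 211 or vehicle 162 or 165, 3 without vehicle 161, 164 or 166 and 10 without 209. S100a9 stood at 0.221 without 211, and Cdo1 at 0.364 without 210. In the sex difference 10 probes passed, led by Hsd3b (7.40 ± 0.94), Cyp11a1 (6.28 ± 0.95), Star (5.33 ± 0.81), Cyp11b3 (4.75 ± 0.90) and Cyp1b1 (3.77 ± 0.73), and 1 passed without male 155. Of these Hsd3b, Cyp11a1 and Cyp11b3 were open to carry-over in both sexes and Star in females.

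Male thyroid changed 24 probes (22 higher, 2 lower), 10 without replicate 159, which held B cell transcripts, and 12 without 158. Hmgb2 rose from 524 ± 168 to 1550 ± 262 CPM (1.56 ± 0.32, adjusted p = 0.00331, 5 of 5 libraries). Igj (4.68 ± 0.80, 0.65 without 159) and S100a8 (2.74 ± 0.72, 0.162 without 156) rose and Fos (-1.65 ± 0.43, 0.205 without vehicle 112) and Pcolce (-0.62 ± 0.16, 0.167 without 158) fell. DESeq2 called 70 (47 higher, 23 lower). In female thyroid 1 probe, Hsd3b (1.74 ± 0.22, open to carry-over), changed, with 144 at an unadjusted p under 0.05. That count was 2 without vehicle 161 or 166, 3 without 208 or vehicle 163 and 4 without 209, and DESeq2 called 5 (3 higher, 2 lower). The sex difference held 18 probes, led by Igj (5.52 ± 1.24), LOC500183 (6.16 ± 1.45), LOC680329 (6.18 ± 1.47, open to carry-over in females), Rps27a (1.07 ± 0.25) and Rps19 (0.99 ± 0.24). It was 0 without male 159, female 211 or female vehicle 161, 11 or 4 without male 156 or 158, 9 or 8 without male vehicle 110 or 107, 3 without female 209, and 6 or 10 without female vehicle 164 or 167. By DESeq2 it was 29 (28 higher in males, 1 lower, against 13 and 5), and 237 probes had an unadjusted p under 0.05.

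Brain changed 8 probes in females and 6 in males. In females Gpd1 rose from 148 ± 56.9 CPM by 1.74 ± 0.34 (adjusted p = 0.00244, 0.0678 without 208), with Gpatch4 (1.14 ± 0.22, 0.0713 without 210) and LOC100912163 (0.77 ± 0.18, 0.996 without 209). Hsd3b (1.37 ± 0.24) rose and Lyz2 (-1.23 ± 0.24) and Cd3d (-1.88 ± 0.46, 0.474 without 209) fell, open to carry-over, and T cell markers fell in 1 of 4 probes (0.000646, and 0.0112 with an estimated correlation). The count was 5 without 209 or vehicle 165 or 167. In males Cps1 rose from 5.11 to 23.8 CPM (2.19 ± 0.49, 0.0871 without vehicle 112), and the open probes Tg (5.81 ± 1.15), LOC500183 (4.20 ± 0.84, 0.0819 without 158) and Rup2 (3.44 ± 0.81, 0.885 without 155) rose and Cyp2b1 fell (-1.98 ± 0.45, 0.127 without vehicle 111). That count was 2 without 155 or 156, 1 without 157 and 3 without vehicle 111, and DESeq2 called 14 (11 higher, 3 lower). The 1 probe with a sex difference was Stx4 (-1.02 ± 0.21, adjusted p = 0.0144). Without male 156, 158 or 159, female 209 or female vehicle 160 or 167 none passed, without male vehicle 114 it was 3, by DESeq2 3 (2 higher in males, 1 lower), and 155 had an unadjusted p under 0.05.

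Ovary changed 16 probes (12 higher, 4 lower), which was 1 without replicate 211, 4 without 209 and 34 without 208. Cbr1 rose from 2340 ± 688 to 7280 ± 4750 CPM (1.63 ± 0.36), with Runx1 (2.14 ± 0.53) and Vegfa (1.32 ± 0.30), and without 209 the adjusted p of these stood at 0.571, 0.864 and 0.809. Hspa1l, open to carry-over, also rose (2.40 ± 0.51, 0.0784 without 211). S100a8 (3.05 ± 0.68) and S100a9 (2.16 ± 0.46) rose in replicate 211, without which their adjusted p was 0.99 and 0.962. RT1-A2 (-1.28 ± 0.33) and Gsta4 (-0.65 ± 0.16) fell, both at 0.261 without 209 and RT1-A2 again a probe linked to the animal, and Myl2 (-2.36 ± 0.41) and LOC259245 (-2.46 ± 0.54, 0.0784 without 211) fell, open to carry-over. Uterus changed 7 probes (6 higher, 1 lower), with Hsd3b, open to carry-over, down by 2.00 ± 0.24. LOC290595 (8.45 ± 1.47) and Il1a (5.84 ± 1.39) rose in replicate 211, without which their adjusted p was 0.832 and 0.896. That count was 1, 27, 11 or 19 without replicate 211, 210, 208 or 209 and 4 without vehicle 166, and DESeq2 called 21.

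Testis changed 35 probes (29 higher, 6 lower), 19 without replicate 158. Hdac2 fell from 2380 ± 477 to 1580 ± 333 CPM (-0.59 ± 0.14, adjusted p = 0.0126, 0.0657 without 157), with Lipa (-0.71 ± 0.17, 0.092 without 158), St3gal5 (-0.60 ± 0.16, 0.257 without 158) and Thy1 (-1.90 ± 0.42, open to carry-over). The rises were at trace levels: Amy2a3 reached 9.07 CPM and Cyp3a1 10.0, and the open probes Myl2 51.3, Sult2a2 20.2 and Cyp2c6v1 18.4 (0.0958 without 158). The CAR and PXR list (2 of 16 up, 4 alone, adjusted p = 0.0144), the sex-biased list (1 of 8 up, 0.0218) and the skeletal muscle list (0 of 5, 1 alone, 0.0206) were each at 0.255 with an estimated correlation. No list passed in female lung, ovary, thyroid or uterus or in male brain, heart, lung or thyroid.

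**Figure D3:**
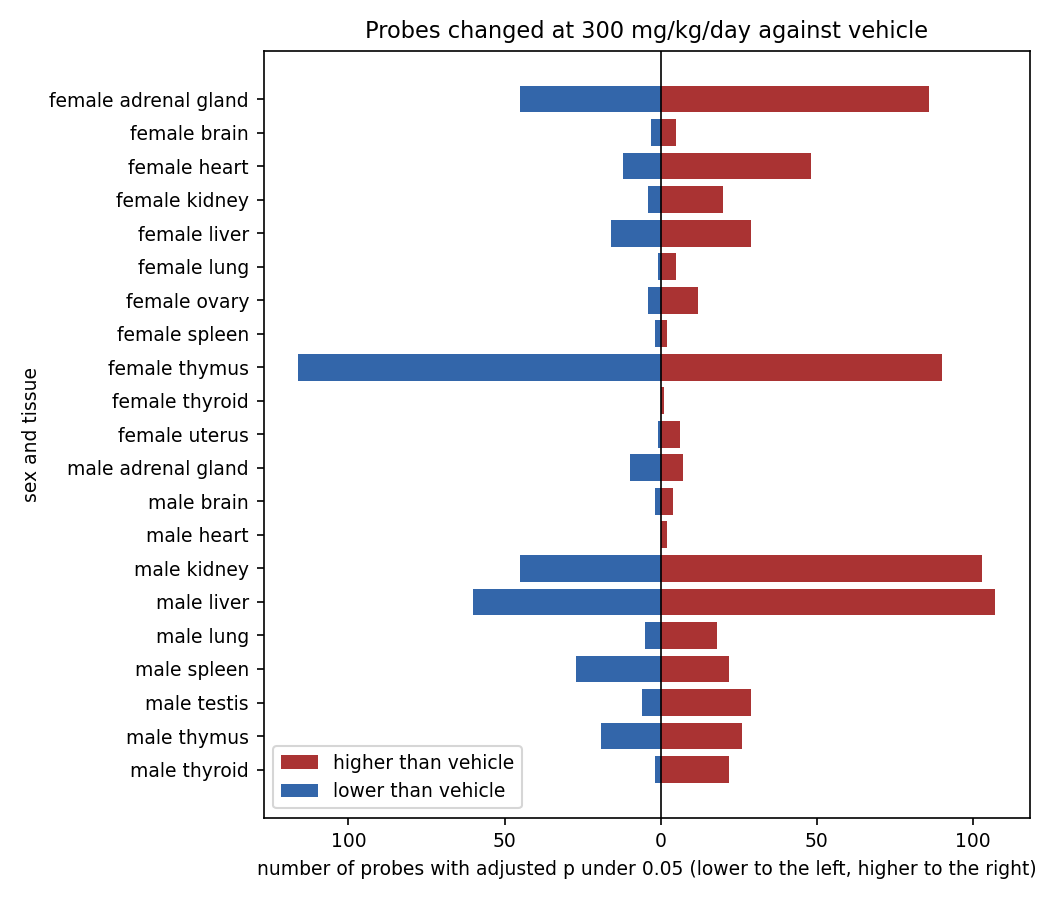
Number of probes that changed at 300 mg/kg/day in each of the 21 sets, with bars to the right for higher and to the left for lower than vehicle. Female thymus (206), male liver (167), male kidney (148) and female adrenal gland (131) had the longest bars.

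Below 300 mg/kg/day 875 changes were called over all sets and doses. Outside liver and kidney the counts of at least 20 rested on single animals. Male adrenal gland at 3 mg/kg/day gave 153 probes (103 higher, 50 lower), with the kidney transcripts Dao (6.00 ± 1.01, open to carry-over) and Acy3 (2.24 ± 0.38) up and Cyp11b3 down (-1.25 ± 0.30, adjusted p = 0.0101), and 28 without replicate 136 (where Dao stood at 0.0641 and Acy3 at 0.0725), 96 without 138 and 100 without vehicle 107. At 1 mg/kg/day it gave 27, all higher, with Igfbp3 (1.93 ± 0.37) and Col3a1 (1.57 ± 0.39), but 1, 2, 55 or 44 without 131, 132, 130 or 133 and 11, 4 or 5 without vehicle 111, 107 or 112. Male heart at 1 mg/kg/day gave 63 (59 higher, 4 lower) with Gatm (4.86 ± 0.69) and Dao (6.70 ± 1.18, open to carry-over), and none by edgeR without 133. Kidney transcripts were held by replicate 136 in adrenal gland and by 133 and 134 in heart. Male thyroid at 0.3 mg/kg/day gave 44 (43 higher, 1 lower) with Hsd3b (7.38 ± 0.94) and Star (6.99 ± 0.99), open to carry-over, and 0 without 128, which held adrenal transcripts. Replicate 127 held heart and liver transcripts. The count was 85 without 125 and 101 without 129. Male brain at 0.3 mg/kg/day gave 23 (20 higher, 3 lower) with Fstl1 (1.25 ± 0.24) and Ccl7 (4.46 ± 0.90, 0.479 without 129). That count was 2, 46 or 41 without 129, 126 or 127, and 11, 4, 9, 8, 7 or 14 without vehicle 107, 108, 109, 111, 112 or 114.

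Male thymus at 0.1 mg/kg/day gave 96 changes (88 higher, 8 lower) with Lig4 (1.43 ± 0.29) and Calcoco1 (1.28 ± 0.25, adjusted p = 0.0071, 0.653 without 124). It gave 0 without 124, 212 without 120, 163 without 123 and 60, 46, 58, 55 or 60 without vehicle 108, 109, 110, 112 or 113. Female thymus at 3 mg/kg/day gave 22, all lower, among them the liver and muscle transcripts Alb (-5.20 ± 1.15) and Ckm (-5.62 ± 1.23), open to carry-over. It gave 0 without 188, 189, 190 or 192, 10 without 191, 3 without vehicle 161 and 34 without vehicle 166.

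Traces of other tissues followed the dose group in some sets. The sum of 3 heart transcripts was 30.3 to 87.6 CPM in the 9 livers at 300 mg/kg/day and at most 8.70 CPM in the 94 other livers. Of 19 sets that are not heart, 2 had every 300 mg/kg/day library above all other doses and 3 had every one below. The SD of log2 levels over the sets was 0.507 times that in vehicle. Single libraries at vehicle or 300 mg/kg/day held another tissue beyond those named above. They were female spleen vehicle 160 and 161, female uterus vehicle 164, male heart 158 and vehicle 111, male lung vehicle 114 and male thyroid vehicle 107 and 110 (liver), female thyroid 210 and vehicle 165, male brain 159 and male thyroid 156 (heart), male heart vehicle 110 (testis) and male lung vehicle 110 (kidney).

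**Figure D4:**
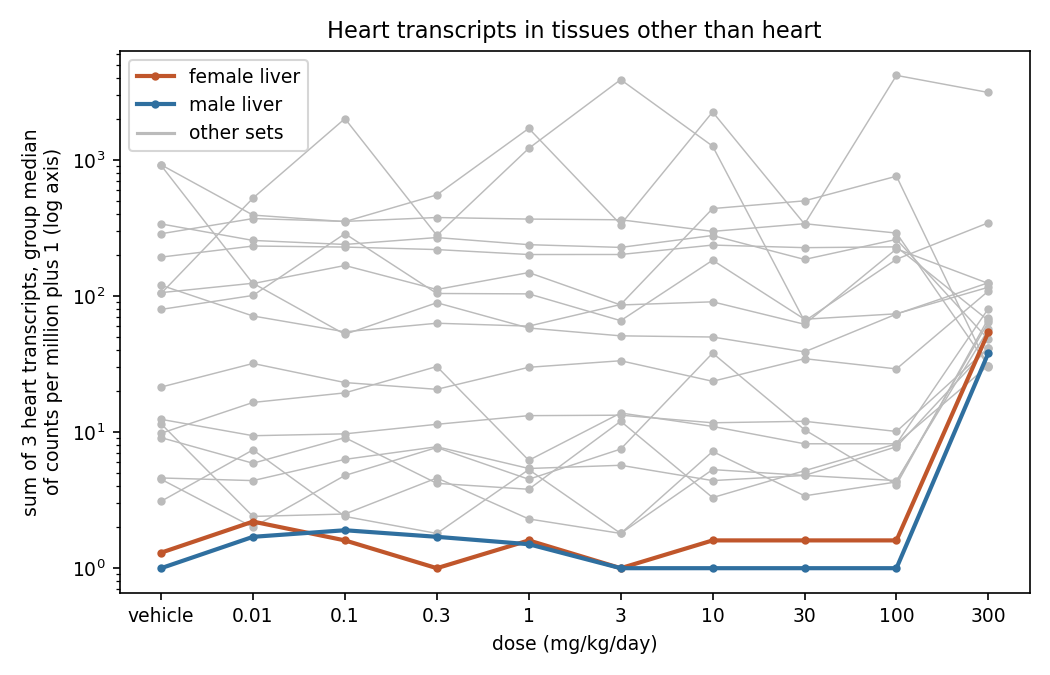
Summed CPM of 3 heart transcripts by dose on a log axis, with 1 line per set and points for the median of its dose group plus 1. Liver sets lie low at all doses but 300 mg/kg/day, where single livers had 30.3 to 87.6 CPM.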

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

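The tests of the 3 patterns weighed here, and the choice of lower doses for other splits of the samples, were made only after the results were seen.

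Some libraries stood far from the rest of their group in total counts. The gap of the outermost log2 total to its neighbour was divided by the range of the group. This ratio passed the 95% critical value of Dixon's test in 19 of 207 groups (9.18%), where chance passes about 1 in 20 groups, or 10.3. The lowest totals that passed were those of female lung vehicle 161 (0.669), female ovary 185 at 1 mg/kg/day (0.728) and male thymus 141 at 10 (0.851). The highest were those of female adrenal gland 181 (0.827), female brain 180 (0.726), female ovary 181 (0.719), female uterus 181 (0.783) and male testis 127 (0.881) at 0.3 mg/kg/day, and of male adrenal gland 115 at 0.01 (0.716), female thymus 184 (0.721) and male liver 132 (0.783) at 1. Further high totals were those of male lung 136 (0.71) and male thyroid 136 (0.767) at 3, male heart 147 (0.881) and male lung 147 (0.928) at 30, female lung 205 (0.78), male lung 154 (0.775) and male testis 154 (0.747) at 100, and male spleen 159 at 300 (0.912).

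Of 470 groups of log2 CPM values of the named genes, with 1 added to each CPM, 38 passed the same value (8.09%, where 1 in 20 is 23.5). In male liver these were Star in vehicle 114 (1.0), Mlf1 in vehicle 110 (0.636) and replicate 155 (0.853), Acaa1a in 155 (0.719), C1r in 156 (0.846) and Ahsg in 159 (0.711). In female liver they were A2m (0.847) and Acaa1a (0.906) in 208, Myl2 in vehicle 162 (0.605) and Cyp17a1 in vehicle 161 (0.573). Kidney gave Amy2a3 in male vehicle 114 (1.0), Cyp4a1 in male vehicle 110 (0.547), Acaa1a in male 156 (0.766), LOC679794 in male 157 (0.813) and Cebpd in female vehicle 167 (0.663). Adrenal gland gave Fabp1 (0.907), Gbp4 (0.872) and Dbp (0.873) in female 209, Cpt2 in female vehicle 160 (0.558) and Tg in male 158 (0.759). Heart gave Thrsp (0.878) and S1pr3 (0.849) in female 211 and S100a9 in female vehicle 165 (0.545). Thymus gave Cd74 in female vehicle 161 (0.625), Pgam2 in female vehicle 164 (0.874) and Ccna2 in female 210 (0.858). Brain gave Hsd3b in female vehicle 162 (0.669), LOC100912163 in female 209 (0.866) and Tg in male vehicle 107 (1.0). Lung gave Hsd3b in female 208 (0.85), Prdx3 in male 155 (0.801) and Cd3g in male vehicle 111 (0.6). The others were Igj in male thyroid 159 (0.77), Fos in male thyroid vehicle 112 (0.534), Lipa (0.803) and St3gal5 (0.822) in testis 158, S100a8 in ovary 211 (0.886) and Il1a in uterus vehicle 160 (0.709). A ratio of 1.0 means that all other libraries of the group were tied, which near the floor can rest on few reads. The rate of 1 in 20 need not hold for such groups.

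In 43 pairs of a named gene and a tissue the log2 response differed between the sexes by the interaction test at an adjusted p under 0.05. Values are given as male minus female. In liver these were Ehhadh (3.50), Cyp4a1 (3.35), Eci1 (2.46), Acaa1a (2.42), St6galnac2 (4.88), Fam183b (5.45) and Hspa1l (7.78). In kidney they were Tg (6.33), Myh4 (7.20), Myh1 (5.80), Sec24d (-0.92) and Aebp1 (-1.94), and in adrenal gland Tg (-10.4), Hmgb2 (1.83), Nmt1 (-0.88), Hsdl2 (-0.99) and Ckm (-4.04). In heart they were Tagln (-5.25), Acta2 (-4.71), Tpm2 (-4.55), Cnn1 (-7.79) and Net1 (-2.17), in brain Stx4 (-1.02), and in lung Hsd3b (7.40), Cyp11a1 (6.28), Star (5.33), Cyp11b3 (4.75) and Cyp1b1 (3.77). In spleen they were Hexa (1.63), Hgf (-1.69), Igfbp7 (-0.88), Cenpk (2.91) and Cps1 (2.95), and in thymus Snap25 (3.08), Star (2.21), Hsd3b (1.75), Slc1a2 (1.70) and Mylpf (3.24). In thyroid they were Igj (5.52), Rps27a (1.07), LOC500183 (6.16), LOC680329 (6.18) and Rps19 (0.99).

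Transcripts of other tissues stood at another level at 300 mg/kg/day than at every other dose in several sets. For heart transcripts 3 sets had every library at 300 mg/kg/day below all other doses and 2 had every library above, and the SD over sets of the log2 level was 0.507 times that of vehicle, which restates the pattern. In 7 of the 9 other source tissues this SD was also lower at 300 mg/kg/day than at every other dose, though for lung transcripts it was 1.49 against a next lowest of 1.49. This is in line with carry-over between libraries handled or sequenced together. How libraries were pooled for sequencing is not given in the sources used here, so this remains a hypothesis. A response of these tissues to the compound cannot be told apart from it, since 0 tissues had heart transcripts above all other doses in one sex and below them in the other, and a response could differ in direction between tissues. Tissue picked up at dissection cannot be told apart from it either. Of 21 pairs of a set and an organ that its animals lack, 1, ovary transcripts in male spleen, had every library at 300 mg/kg/day above all other doses, at a sum of 10.0 to 19.7 CPM over 2 probes against at most 7.5. The same 2 probes stood at a median of 102 CPM in testis and 53.9 in male liver, so organs of the male could have supplied them and this value does not decide.

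Some libraries matched another animal than their label at the 31 probes whose level is linked to the animal. The labelled animal was the best match in 95.2% of the 1090 libraries, which says little, since the probes were chosen by their correlation between tissues of the same animal. In 9 libraries, 5 of them with a quality issue, another animal of the same sex stood at least 0.3 higher in correlation. These were tested at 18 further probes of other genes, at which the labelled animal was the best match in 57.6% of all libraries. The same other animal was the best match there in 1 of the 9, female spleen 191 with animal 190 (0.50 against 0.02 for its own), the 1 library where it also stood 0.3 higher. Against noise of the animal profile at these probes alone, the labelled animal was the best match at the further probes in 0 of the 9, where 3.00 were expected at the rates of libraries with and without a quality issue (13.3% and 58.2%; chance of so few 0.0149). Noise of the whole library was not tested. A mislabelled sample stays open, most of all for female spleen 191, as the further probes are few. Without a quality issue the 9 included female ovary 172, female spleen 191, male spleen 149 and female thymus 202, none of them in vehicle or at 300 mg/kg/day. No biological explanation was tested.

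Kidney transcripts were among the genes changed at 3 mg/kg/day in male adrenal gland and at 1 mg/kg/day in male heart. In male heart 3 of 5 libraries lay at or below the highest vehicle library, and the median library stood 0.45 log2 over the set median against 1.26 for that vehicle library, which argues against a response to the compound. In male adrenal gland 3 of 5 lay above it and the median library stood at 0.34 against 0.30, so there a response cannot be told apart from kidney tissue. Without the libraries with kidney transcripts at over 8 times the set median, 153 probes became 28 in adrenal gland (replicate 136 left out), a ratio of 5.46, and 63 became 0 in heart (133 and 134 left out). This is in line with kidney tissue in single libraries.

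The libraries of each comparison were also split at random into groups of the same sizes, with the real split counted among the 100, or 50 for the sex difference. At 300 mg/kg/day no other of the 100 splits reached the real count in female adrenal gland (131, highest other 5), heart (60, 50), ovary (16, 9) and thymus (206, 42), nor in male adrenal gland (17, 2), brain (6, 2), heart (2, 1), kidney (148, 30), lung (23, 19), spleen (49, 29), testis (35, 15), thymus (45, 32) and thyroid (24, 7). As many probes came in 3 splits, the real one included, in male liver (167, 245), female liver (45, 225), female brain (8, 14) and female spleen (4, 6). Chance was excluded in all of these. It was not excluded in female kidney (18 splits, 24, highest other 41), lung (9 splits, 6, 294), thyroid (12 splits, 1, 3) and uterus (12 splits, 7, 25). For the trend chance was excluded in male liver (1 split, 88, 51), female liver (2 splits, 7, 138) and male kidney (1 split, 110, 20), but not in female kidney (18 splits, 4, 71).

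For the sex difference only the real split of 50 reached the count in adrenal gland (32, highest other 7) and heart (31, 16). The same held in kidney (51, 22), lung (10, 9) and thyroid (18, 8). In liver (73, 76) and spleen (5, 5) 2 splits did, the real one included. In brain (15 splits, 1, 4) and thymus (3 splits, 13, 75) at least 5% of splits were as large. With 9 tissues tested, single ones could fall under 5% by chance. Below 300 mg/kg/day most groups were picked for their counts among 168 comparisons, of which 8.40 are expected by chance to have under 5% of splits as large. With 9 of the 13 groups tested so placed, chance is not excluded for the groups picked. They were male liver at 30 (1 split, 25, 5) and 100 (2 splits, 18, 240), male kidney at 100 (2 splits, 21, 188), male adrenal gland at 1 (2 splits, 27, 51) and 3 (1 split, 153, 27), male brain at 0.3 (2 splits, 23, 23), male thymus at 0.1 (4 splits, 96, 235), female kidney at 0.3 (2 splits, 80, 93) and female thymus at 3 (1 split, 22, 16). At least 5% of splits were as large in male heart at 1 (9 splits, 63, 118), male thyroid at 0.3 (21 splits, 44, 107), female kidney at 100 (32 splits, 2, 51) and female liver at 100 (6 splits, 1, 2). Over 3 times the real count was reached by 3 splits in female lung, 2 in uterus, 1 in female liver and for its trend, 9 for the trend in female kidney, 2 for the sex difference in brain and 1 in thymus. At 100 mg/kg/day it was reached by 29 splits in female kidney, 1 in male kidney and 1 in male liver. Such splits point to a structure of the samples, and what it is was not tested.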

How the results depend on the processing

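The fits without probes open to carry-over, without libraries holding another tissue, and with 1 library left out at doses below 300 mg/kg/day or for benchmark doses were chosen only after the data were seen. The other alternatives were set before the data were examined. No paired analysis was possible because the dose groups within a tissue share no animal. Counts are of changed probes, as the count with all used libraries by edgeR and TMM followed by the count under the alternative.

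RLE size factors in place of TMM left each count at 300 mg/kg/day within 1.5 times, and moved the sex difference in brain from 1 to 0 and in spleen from 5 to 9. DESeq2 at 300 mg/kg/day raised female heart from 60 to 103, kidney from 24 to 42, liver from 45 to 75, thyroid from 1 to 5 and uterus from 7 to 21, and male adrenal gland from 17 to 31, brain from 6 to 14, lung from 23 to 44, thymus from 45 to 70 and thyroid from 24 to 70. It raised the sex difference in brain from 1 to 3, heart from 31 to 83, kidney from 51 to 87, spleen from 5 to 21 and thyroid from 18 to 29, and the changes at lower doses from 875 to 1539. With no filter on low counts female uterus went from 7 to 15, male kidney from 148 to 350, testis from 35 to 106 and male thymus from 45 to 22, the sex difference in brain from 1 to 2, spleen from 5 to 8 and thymus from 13 to 6, and the trend in female liver from 7 to 33 and male kidney from 110 to 285.

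With quality-issue libraries kept, female adrenal gland went from 131 to 27, ovary from 16 to 6, spleen from 4 to 173 and thymus from 206 to 133, and male adrenal gland from 17 to 0, brain from 6 to 3, heart from 2 to 0, spleen from 49 to 11 and thymus from 45 to 7. The sex difference went from 32 to 2 in adrenal gland, 1 to 15 in brain, 31 to 16 in heart, 5 to 137 in spleen, 13 to 7 in thymus and 18 to 31 in thyroid, and lower doses went from 875 to 3023. A fit to vehicle and 300 mg/kg/day libraries alone, with fewer samples to estimate the spread, took female adrenal gland from 131 to 76, brain from 8 to 1, heart from 60 to 21, liver from 45 to 10, lung from 6 to 2, ovary from 16 to 2, spleen from 4 to 1 and uterus from 7 to 1, and male liver from 167 to 81, lung from 23 to 2, testis from 35 to 15, thymus from 45 to 77 and thyroid from 24 to 115. The sex difference went from 1 to 0 in brain, 31 to 9 in heart, 73 to 32 in liver, 10 to 0 in lung, 5 to 1 in spleen, 13 to 5 in thymus and 18 to 1 in thyroid.

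Without probes open to carry-over female brain went from 8 to 2, spleen from 4 to 0, thyroid from 1 to 0, and male brain from 6 to 0, heart from 2 to 1, lung from 23 to 9 and thymus from 45 to 13. The sex difference went from 51 to 26 in kidney, 73 to 47 in liver, 10 to 5 in lung and 13 to 0 in thymus, and the trend in female liver from 7 to 3. Without libraries holding another tissue female uterus went from 7 to 12, male heart from 2 to 1, liver from 167 to 78, lung from 23 to 1 and thyroid from 24 to 9. The sex difference went from 1 to 0 in brain, 31 to 15 in heart, 51 to 22 in kidney, 73 to 46 in liver, 10 to 0 in lung, 13 to 6 in thymus and 18 to 1 in thyroid, and lower doses went from 875 to 566. The gene list tests that passed went from 42 of 597 to 9 with an estimated correlation and to 27 without open probes. In these fits with fewer probes or libraries the smaller number tested is part of the change, and for all others the cause was not tested.

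For the trend, the slope on the dose in mg/kg/day gave 139 in place of 88 in male liver, 92 for 7 in female liver, 201 for 110 in male kidney and 28 for 4 in female kidney. Without the 300 mg/kg/day group these were 18, 1, 2 and 2. Benchmark doses without that group were 19.0 in place of 113 mg/kg/day in male liver, 3.35 for 123 in female liver, 17.4 for 99.7 in male kidney and 26.1 for 82.3 in female kidney. A larger response size gave 176 in male liver, 162 in female liver and 136 in male kidney. Male liver also moved to 64.4 with no fold filter, 38.9 with quality-issue libraries kept, 65.1 without open probes and 38.9 without libraries holding another tissue. The cause was not tested.

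Leaving out each library in turn at 300 mg/kg/day gave ranges of 55 to 147 in female adrenal gland, 5 to 9 in brain, 9 to 116 in heart, 13 to 40 in kidney, 19 to 62 in liver, 2 to 10 in lung, 1 to 34 in ovary, 3 to 6 in spleen, 75 to 236 in thymus, 1 to 4 in thyroid and 1 to 27 in uterus. In males they were 8 to 20 in adrenal gland, 1 to 6 in brain, 2 to 2 in heart, 105 to 173 in kidney, 78 to 336 in liver, 4 to 41 in lung, 17 to 105 in spleen, 19 to 37 in testis, 1 to 97 in thymus and 10 to 26 in thyroid. The sex difference ranged from 14 to 37 in adrenal gland, 0 to 3 in brain, 0 to 75 in heart, 6 to 79 in kidney, 45 to 177 in liver, 1 to 12 in lung, 0 to 13 in spleen, 4 to 33 in thymus and 0 to 20 in thyroid. The trend ranged from 59 to 107 in male liver, 4 to 12 in female liver, 68 to 174 in male kidney and 2 to 6 in female kidney, and benchmark doses from 38.2 to 124, 101 to 164, 78.2 to 138 and 0.0016 to 103 mg/kg/day. At lower doses ranges were 0 to 57 at 30 and 11 to 20 at 100 in male liver, 7 to 34 at 100 in male kidney, 3 to 207 at 0.3 and 1 to 18 at 100 in female kidney, 0 to 34 at 3 in female thymus, 1 to 55 at 1 and 28 to 153 at 3 in male adrenal gland, 2 to 46 at 0.3 in male brain, 0 to 73 at 1 in male heart, 0 to 212 at 0.1 in male thymus and 0 to 101 at 0.3 in male thyroid. Female liver at 100 stayed at 1. The libraries that moved a count over 1.5 times are named beside each count.

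With 1 library left out in turn A2m in female liver (2.04 with all) ranged from -0.27 without replicate 208 to 2.38, and S100a8 in ovary (3.05) from -0.10 without 211 to 3.44. In male thyroid at 0.3 mg/kg/day Hsd3b (7.38) ranged from -0.19 to 7.70 and Star (6.99) from 0.00 to 7.31, both lowest without 128. LOC500183 in the sex difference of thyroid (6.16) ranged from -0.23 without male 159 to 6.88. Without libraries holding another tissue Dao in male heart at 1 mg/kg/day became -0.38, Cyp11a1 in male lung -1.65 and Star -0.45, and Star and Hsd3b in male thyroid at 0.3 mg/kg/day became -0.13 and -0.47. In the sex difference of lung Hsd3b became -0.03, Cyp11a1 -0.90, Star -0.16, Cyp11b3 -1.24 and Cyp1b1 -0.45, and LOC500183 in thyroid -0.36. Each of these calls rested on the libraries left out. Of the other values of single genes and lists under an alternative, 1848 stayed on their side of the threshold, 315 lost the call, 6 gained one and 50 counts or medians moved, and with 1 library left out these numbers were 4059, 677, 8 and 66.

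Depth set the floor of detection, where 3 counts stood for up to 5.74 CPM. With the group sizes and depths of the sets, simulated 2-fold changes were recovered for a median of 56.7% of changed probes at 300 mg/kg/day. The simulated counts held no other tissue and no correlation between probes.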

Other observations

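Liver and kidney of the same animals shared changed genes at 300 mg/kg/day. In males 15 probes rose in both, against 3.90 for independent lists, among them Acaa1a, Agmo, Cd81, Cyp11a1, Cyp4a1, Eci1, Ehhadh, Fabp1, Fstl1, Hsd3b, S100a9, Star and Vnn1, of which Cyp11a1, Hsd3b and Star were open to carry-over in both organs. A further 5 fell in both, against 1.52: Echs1, Fmo1, Paqr9, Ptprk and Pygl. Of these Echs1 acts in mitochondrial beta oxidation and Pygl in glycogen use. They are single genes, and Eci1, also of mitochondrial beta oxidation, rose in both organs. In females 7 rose in both, against 0.32: Acaa1a, Eci1, LOC100909675, Vnn1 and the open probes Hsd3b, Myl2 and Star. No probe fell in both by edgeR, against 0.01. The organs come from the same animals, so differences between animals may add to the overlap, as in female liver, where the call of Acaa1a ended (adjusted p = 0.656) without replicate 208.

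Hist1h4a and Hmgb2 rose in several organs at 300 mg/kg/day. Hist1h4a rose by 2.11 ± 0.23 in female thymus, 1.37 ± 0.16 in male adrenal gland and 1.32 ± 0.30 in male lung. Hmgb2 rose by 1.56 ± 0.32 in male thyroid and in both livers, where it was open to carry-over, and fell in female adrenal gland. The quality-issue libraries had totals of 54934 to 1630371 counts.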
